A study of Mus musculus with 8 samples.

How the data were processed

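Messenger RNA libraries of PBMC of C57BL/6 mice, 4 of the T2DM and 4 of the control group, were analysed from 1 table of raw counts per gene symbol. Per the labels' protocols, total RNA was extracted with TRIzol and paired-end libraries were made with an ABclonal mRNA kit; whether the kit keeps strand is not given in the sources used here. Per the submitters' processing notes, HISAT2 and featureCounts were used, with no versions named. The genome build and annotation are not given in the sources used here, so no coordinates are reported, and overlapping and antisense genes cannot be told apart. The deposited counts are whole numbers and were not normalized by the authors, as far as their values show.

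The table holds 30751 rows. The 238 rows without a gene name, which took between 0.00229% and 0.00908% of a library's counts, were left out, and rows of the 28 symbols that occur more than once were summed. Each column was matched to its sample by its title, and all 8 were used. Depth ranged from 11295892 to 24276898 counts per library. A value of 3 counts is worth 0.58 CPM after scaling in T2DM 1 and 0.075 CPM in T2DM 4. Low genes are therefore measured less precisely in T2DM 1. The library pair that differed least had a chi-square of 15.8 per degree of freedom, so no 2 libraries were treated as repeats of one. Replicate numbers 1 to 4 recur in both groups. Correlations between the same-numbered libraries of the 2 groups, after removal of group means, were -0.51, -0.58, -0.62 and -0.27, so numbers were not used to pair libraries.

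Genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided) after filterByExpr with a minimum count of 10 and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. Log2 CPM used a prior count of 2. The common dispersion was 0.171, a coefficient of variation between libraries of 0.414. TMM factors ran from 0.458 (T2DM 1) and 0.496 (T2DM 3) to 1.65 (T2DM 4). On simulated counts with the real means and library sizes, 14 of 100 genes changed 2-fold and 77 of 100 changed 4-fold were recovered, with 4 false among 96 calls, over 14825 tested genes. With no change simulated 0 genes and 0 lists were called. Each gene was drawn independently, without the correlation between genes of real libraries. The simulation therefore cannot show how often lists or genes are called by chance in these data.

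The design, the gene lists, the naming rule and all other settings tried, except those named below as added, were fixed before the data were examined. Named genes are the 12 with the largest positive and the 12 with the largest negative log2 fold change among called genes whose groups do not overlap in CPM, with a mean of at least 2 log2 CPM and a symbol that is not a predicted model, a pseudogene or an antigen receptor segment. For each list described, called members and up to 4 members with the smallest p are named as well; 1 called member of a list is not reported here. Of 38 gene lists from textbook knowledge, 37 with at least 5 tested members were tested with limma 3.58.1 camera (preset correlation 0.01), with camera at an estimated correlation and with fry; the list of sex-linked genes served only as a check of labels, and none of its 4 tested genes changed. Shares of counts were compared by exact two-sided permutation over 70 arrangements, for which 0.0286 is the smallest p, with adjustment over 6 measures.

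Alternatives were another scaling (the median-of-ratios factors of DESeq2, or none), DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 4 libraries, the replicate number as a block, stricter thresholds, leaving out haemoglobin, immunoglobulin and mitochondrial genes, and leaving out each library. Added after seeing the data were fits without T2DM 1 and T2DM 3 and with platelet and erythroid means as covariates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.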

Results

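Messenger RNA was sequenced from peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes of the blood, of wild-type C57BL/6 mice. The series holds 8 libraries, 4 from mice with type 2 diabetes (T2DM) and 4 from control mice of matching age. Libraries held between 11295892 counts (T2DM 1) and 24276898 counts (T2DM 4), and the deposited table gives a raw count per gene symbol. Which diabetes model was used is not in the labels. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, which could be technical if they did not.

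The blood samples were not of one composition. Haemoglobin genes took 4.34% ± 4.23 of counts in the control libraries and 16.1% ± 15.3 in the T2DM libraries (SD, n = 4 each; exact two-sided permutation p = 0.229, adjusted p = 0.457). T2DM 1 (31.8%) and T2DM 2 (26.6%) held the highest haemoglobin shares, and control 2 held 10.3%. Immunoglobulin genes took 0.557% ± 0.112 of counts in the control libraries and 0.299% ± 0.202 in the T2DM libraries (SD, n = 4 each; exact permutation p = 0.0857). Without T2DM 4 the exact permutation p of the immunoglobulin difference was 0.0286. Mitochondrially encoded genes took 5.32% ± 1.31 and 5.54% ± 3.21 of counts (SD, n = 4 each; exact permutation p = 0.914), and ribosomal protein genes 3.57% ± 0.759 and 2.43% ± 1.65 (exact permutation p = 0.314, n = 4 each). The ribosomal difference of -1.14 percentage points ran from -1.85 without T2DM 4 to -0.70 without T2DM 3, and the haemoglobin difference of 11.7 points was 6.49 without T2DM 1. The 10 most abundant genes took 12.8% ± 5.75 and 24.4% ± 14.3 of counts (exact permutation p = 0.229, n = 4 each; p = 0.0286 without T2DM 4, exact), and with haemoglobin genes left out of the total the difference of 11.6 percentage points became 1.43 (exact p = 0.714). Genes with at least 1 count numbered 23621 ± 1138 and 22714 ± 2045 (SD, n = 4 each; exact permutation p = 0.4). None of these 6 measures passed after adjustment, the lowest adjusted p being 0.457.

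**Figure D1:**
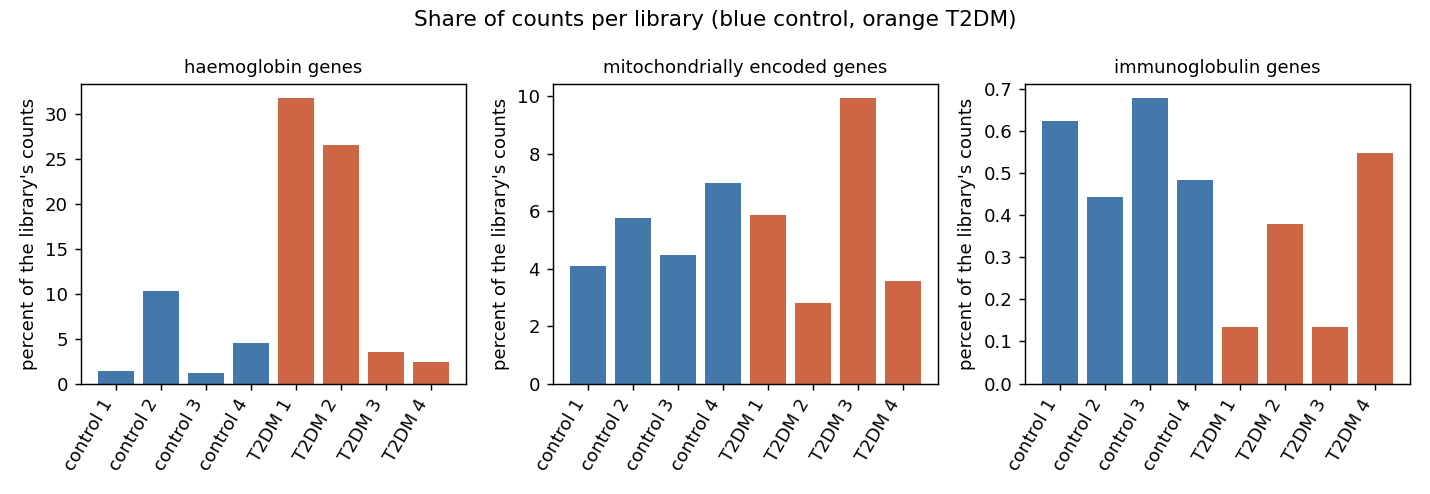
Percent of each library's counts in haemoglobin, mitochondrially encoded and immunoglobulin genes, 1 bar per library, blue for control and orange for T2DM. Haemoglobin reached 31.8% in T2DM 1 and 26.6% in T2DM 2, while T2DM 3 held the highest mitochondrial share, 9.94%.

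Platelet genes and the axis of largest variance did not follow the groups. The first principal component of log2 CPM held 60.1% of the variance and placed T2DM 1 and T2DM 3 at one end and T2DM 2 and T2DM 4 at the other. The mean log2 CPM of the platelet and megakaryocyte list was 11.7 in T2DM 1 and 12.4 in T2DM 3, against 7.58 in T2DM 2 and 7.71 in T2DM 4, with the control libraries between 8.74 and 10.7. Red cell genes did not follow this order in T2DM 2, which had an erythroid mean 2.33 log2 units above the control mean. Among the control libraries the erythroid means had the same order as the platelet means, from control 2 through control 4 and control 1 to control 3. None of the 18 tested platelet genes passed the gene test. Their median log2 fold change was 1.25 and their camera direction was down (adjusted p = 0.869), so median and test differ in sign. That list was called down without T2DM 3 (median 0.20, adjusted p = 0.041) and without T2DM 1 and T2DM 3 (median -2.31, adjusted p = 8.0e-10). The 18 tested erythroid genes had a median log2 fold change of 1.999 with 0 members past the threshold. As a list they were called up (camera adjusted p = 0.00137; adjusted p = 0.569 with an estimated correlation), with a median of 1.31 without T2DM 1. Without T2DM 1 and T2DM 3 the median was 1.51 and the call was lost (adjusted p = 0.263). The second component, with 18.9% of the variance, placed all 4 T2DM libraries above all 4 control libraries.

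**Figure D2:**
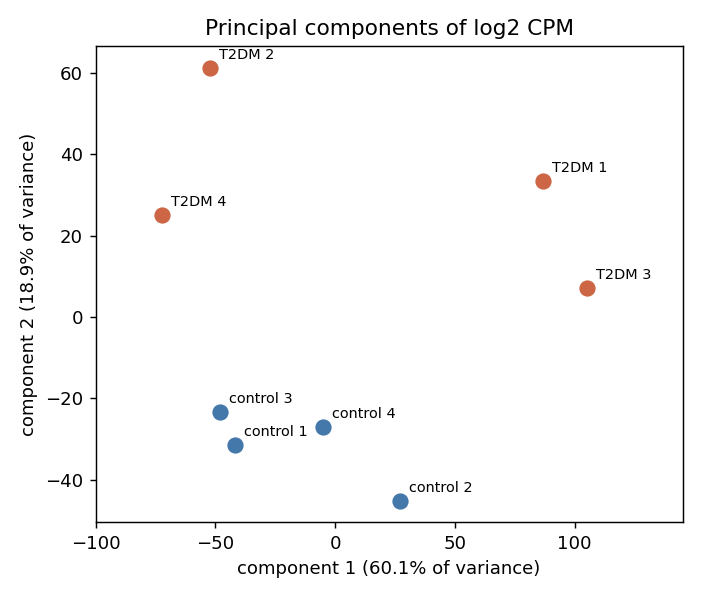
First and second principal components of log2 CPM of the 15392 tested genes, 1 point per library, blue for control and orange for T2DM. The first component (60.1%) spreads the T2DM libraries apart, and the second (18.9%) separates the groups.

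The comparison of T2DM with control mice addresses which blood cell transcripts change in diabetes, in a study of immune ageing under that disease. Granulocyte genes were among the most increased. The neutrophil granule protein genes Ngp, Camp, Ltf and Lcn2 and the myeloperoxidase gene Mpo were higher in each of the 4 T2DM libraries than in any control library, with log2 fold changes from 5.68 to 6.10. Interferon-induced genes were among the most decreased, with Ifi44, Ifi213 and Ifit3 as examples. Of 15392 genes tested, 331 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 284 higher and 47 lower in T2DM. Of these, 244 of the higher and 29 of the lower genes differed by at least 2-fold.

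All 331 genes had groups that did not overlap, as did 1708 of the tested genes (11.1%, against 2.86% expected by chance). The median log2 fold change of all tested genes was 0.12, and without scaling beyond library size it was -0.34, so that small changes near these values are not told from the scaling. The count of 331 changed with each library left out. It was 0 without control 1 (1692 genes at an unadjusted p under 0.05 in edgeR) and 0 without control 3 (1708 such genes). It was 9 without control 2, 49 without control 4, 87 without T2DM 1, 128 without T2DM 2, 218 without T2DM 3 and 542 without T2DM 4. All 331 genes kept their direction and an unadjusted p under 0.05 in each of these 8 fits. They were chosen on the same libraries and had groups that did not overlap, so this was largely fixed by their selection. Without scaling beyond library size 41 genes passed, with DESeq2 902, and without T2DM 1 and T2DM 3, chosen after seeing the data, 445 (222 of them among the 331).

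Among called genes with a mean of at least 2 log2 CPM that met the naming rule, the 12 with the largest increase were Prg2, Mpo, Ngp, Lcn2, Camp, Ltf, Abca13, Itgb2l, S100a8, Olfm4, Ly6g and Lrg1. Ngp rose from 9.98 ± 2.85 CPM in control to 647 ± 576 in T2DM libraries (SD, n = 4 each), a log2 fold change of 6.02 ± 0.88 (SE; edgeR adjusted p = 0.0174). S100a8, a subunit of the calcium-binding protein calprotectin, rose from 12.6 ± 3.87 to 410 ± 236 CPM (log2 fold change 5.03 ± 0.63, edgeR adjusted p = 0.0132). Lcn2, which binds bacterial siderophores, rose from 4.66 ± 1.58 to 271 ± 225 CPM (log2 fold change 5.87 ± 0.85). Mpo had 18 counts in all over the 4 control libraries and 837 over the T2DM libraries (log2 fold change 6.10 ± 0.56, edgeR adjusted p = 0.00687). Prg2, which encodes the major basic protein of eosinophil granules, had 9 counts over the control libraries and 601 over the T2DM libraries (log2 fold change 6.34 ± 0.58). T2DM 4 gave the lowest T2DM value of Ngp (107.8 CPM), Lcn2 (38.8 CPM), S100a8 (96.1 CPM) and Ly6g (2.60 CPM). Each was above all control libraries.

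Under the same rule the 12 genes with the largest decrease were Ifi44, Gbp10, Ifi213, Chst3, Ifit3, Edaradd, Usp18, Ifi214, Ifi206, Cecr2, Ifi27l2a and Ifi208. Ifi44 fell from 11.98 ± 4.29 CPM in control to 1.51 ± 0.854 in T2DM libraries (log2 fold change -2.86 ± 0.44, edgeR adjusted p = 0.0201). Gbp10, a guanylate-binding protein gene induced by interferon, fell from 7.05 ± 1.49 to 1.20 ± 0.437 CPM (log2 fold change -2.49 ± 0.29, edgeR adjusted p = 0.0123). Ifi213, Ifi214, Ifi206 and Ifi208 belong to one family of related interferon-inducible genes, whose reads can be shared between members. Their log2 fold changes were -1.79, -1.41, -1.39 and -1.33. Chst3, a chondroitin sulfotransferase gene, fell from 168 ± 29.6 to 57.0 ± 21.6 CPM. Ifi27l2a fell from 174 ± 25.02 to 66.9 ± 10.1 CPM (log2 fold change -1.38 ± 0.17, edgeR adjusted p = 0.0132).

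**Figure D3:**
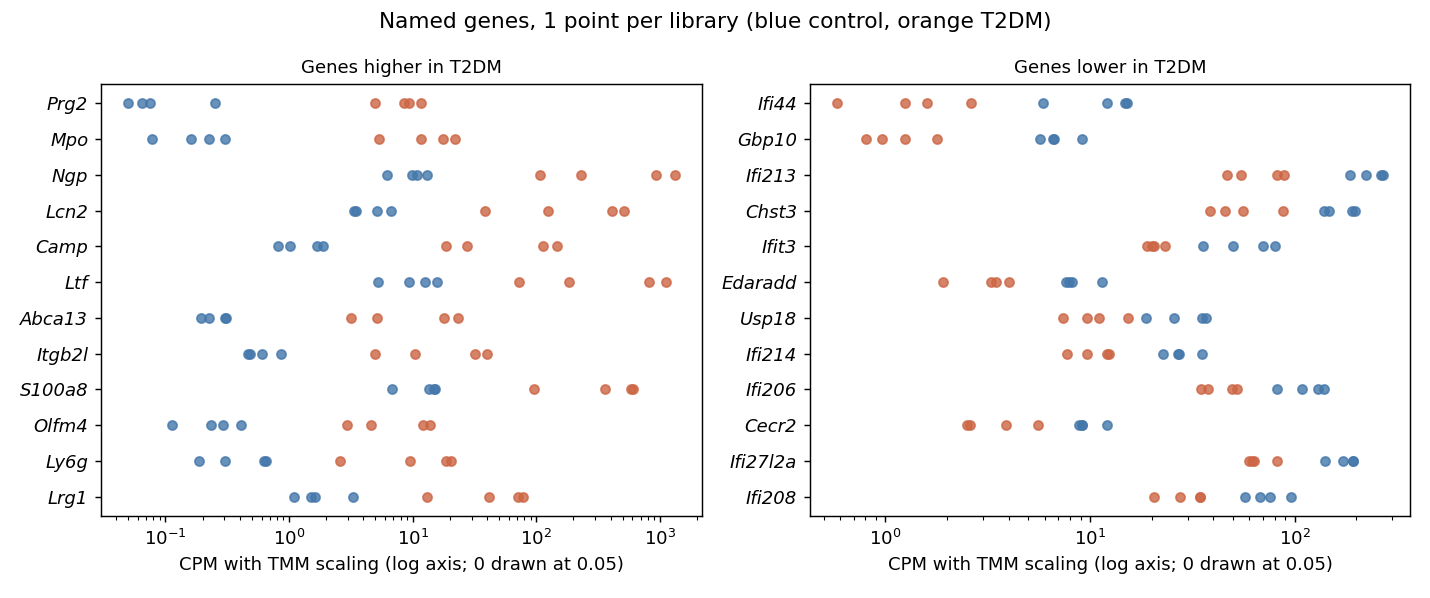
CPM with TMM scaling on a log axis for the 12 named genes higher and the 12 named genes lower in T2DM, 1 point per library, blue for control and orange for T2DM. For each gene the 4 T2DM points lie apart from the 4 control points; Ngp spans 107.8 to 1315 CPM in the T2DM libraries.

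Of the 22 neutrophil genes on a list fixed before the data were examined, 19 rose and none fell, and 22 passed when adjusted over the list alone. Their median log2 fold change was 4.42. S100a9, the partner of S100a8, rose from 60.8 ± 25.2 to 1599 ± 834 CPM (log2 fold change 4.72 ± 0.67). Elane, the neutrophil elastase gene, rose by a log2 fold change of 5.72 from 11 counts over the control libraries to 387. Receptor genes of mature neutrophils rose too, with log2 fold changes of 3.37 for Cxcr2 and 3.13 for Cxcr1. Il1r2, Hdc and Csf3r, named after their values were seen, did not pass (edgeR adjusted p of 0.0596, 0.0619 and 0.0865), with log2 fold changes of 3.79, 2.64 and 2.49. The list was called up (camera adjusted p = 2.0e-26; adjusted p = 0.344 with an estimated correlation; fry adjusted p = 0.00754). List means exceeded the control mean by 4.83, 4.05, 4.28 and 2.53 log2 units in T2DM 1 to 4, and T2DM 1 to 3 also held erythroid means 3.57, 2.33 and 1.67 above the control mean. In T2DM 4 the erythroid mean lay 0.51 log2 units below the control mean (-0.51). The count of 19 was 0 without control 1 or without control 3, 1 without control 2, 2 without control 4 and 11 without T2DM 1.

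Of 18 classical monocyte genes, 7 rose and none fell, and 10 rose when adjusted over the list alone (median log2 fold change 1.13). Chil3, a chitinase-like protein of monocytes and immature granulocytes, rose from 22.1 ± 7.998 to 213 ± 62.1 CPM (log2 fold change 3.26 ± 0.35, edgeR adjusted p = 0.0123). Vcan rose by 4.37, Cd14, the co-receptor for lipopolysaccharide, by 2.38, and Ccr2, the receptor that draws monocytes from the marrow, by 1.69 on the log2 scale. Itgam and Fn1 also rose. The list was called up (camera adjusted p = 3.5e-06; adjusted p = 0.372 with an estimated correlation). The count of 7 was 0 without control 1, 2 or 3, 2 without control 4 or T2DM 2, and 4 without T2DM 1 or T2DM 3. Of 14 tested eosinophil, basophil and mast cell genes, 3 rose: Prg2, Ear6 and Epx. Ear6 went from 12 counts over the control libraries to 185 (log2 fold change 4.58), and Epx, the eosinophil peroxidase gene, from 4 to 253. The list was called up (camera adjusted p = 6.5e-04; adjusted p = 0.344 with an estimated correlation). Its median log2 fold change of 0.78 fell to 0.42 without T2DM 1, 0.30 without T2DM 3 and -0.087 without scaling, the call being kept.

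Progenitor and inflammatory genes rose in part. Of 10 progenitor genes, the granule protease genes Prtn3 (log2 fold change 4.62) and Ctsg (4.50) rose and Ly6a (-0.83) fell. That list was called up (camera adjusted p = 0.0139; adjusted p = 0.553 with an estimated correlation). That call was lost without control 4 (median log2 fold change 1.33 against 1.49, adjusted p = 0.0792), with limma-voom (0.84, adjusted p = 0.110), and without T2DM 1 and T2DM 3 (0.37, adjusted p = 0.399). It was also lost by fry (adjusted p = 0.120). With the call kept the median was 0.90 without T2DM 1 and 0.81 without T2DM 3. Of 22 inflammasome and NF-kB genes, Il1b, Tlr4 and Myd88 rose, with log2 fold changes of 3.49, 1.16 and 0.59. Camera called the list up (camera adjusted p = 0.00166; adjusted p = 0.492 with an estimated correlation), with a median of 0.53 that was 0.34 without control 2 and 0.046 without scaling. Of 18 chemokine receptor genes, Ccr1 (3.23), Cxcr2 (3.37), Cxcr1 (3.13), Ccr2 (1.69) and Ccr6 (0.74) rose on the log2 scale. As a set these genes were called up (camera adjusted p = 0.00647; adjusted p = 0.344 with an estimated correlation), with a median log2 fold change of 0.64 that was 0.34 without T2DM 3, 0.31 with limma-voom and -0.025 without scaling. With platelet and erythroid covariates the median was 0.33 and the call was lost (adjusted p = 0.0683). Of the chemokine receptor genes that rose, Cxcr2, Cxcr1 and Ccr2 were already named with the neutrophil and monocyte genes, so their rise is not a separate result.

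Genes of senescence, the process named in the study's aim, moved both ways. Of 22 tested genes of the senescence and secretory phenotype list, Mmp9 (log2 fold change 3.76) and Il1b (3.49) rose and the chemokine gene Ccl4 (-1.08) fell. Mmp9 is also on the neutrophil list, Il1b on the inflammasome list and Ccl4 on the cytotoxic list. Set against all other genes, the senescence list was up (camera adjusted p = 0.0375, and 0.492 with an estimated correlation). That call was lost without control 1, control 4, T2DM 2 or T2DM 4 (adjusted p from 0.0549 to 0.172), with medians of 0.44 to 0.52 against 0.60. It was also lost with the covariates (0.48, adjusted p = 0.0729), without T2DM 1 and T2DM 3 (0.41, adjusted p = 0.0768) and by fry (adjusted p = 0.0697). Cdkn1a, the cell cycle inhibitor p21, named after its values were seen, stood at 22.8 ± 6.85 and 43.7 ± 20.1 CPM (SD, n = 4 each; log2 fold change 0.94 ± 0.35, edgeR adjusted p = 0.256). None of the 19 p53 and DNA damage genes or the 15 telomere genes passed, and neither list was called (camera adjusted p of 0.858 and 0.169). None of the 19 tested genes of T cell exhaustion and ageing passed (camera adjusted p = 0.245). When adjusted over the list alone, 2 of its genes rose and 2 fell, which a test of 1 direction does not show. Of that list Ctla4 had a log2 fold change of 1.14 and Klrg1 of -0.80 (edgeR adjusted p of 0.103 and 0.0673).

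Of 26 type I interferon response genes, 5 fell and none rose, and 18 fell when adjusted over the list alone (median log2 fold change -0.89). Bst2, which holds budding virions at the cell surface, fell from 54.8 ± 10.9 to 24.2 ± 2.57 CPM (log2 fold change -1.18 ± 0.16, edgeR adjusted p = 0.015). Ifit3, Ifi44, Xaf1 and Usp18, the deconjugase of the ubiquitin-like protein ISG15, also fell, with log2 fold changes of -1.50, -2.86, -1.05 and -1.41. Camera placed this list down (camera adjusted p = 5.5e-15; adjusted p = 0.344 with an estimated correlation). The count of 5 was 0 without control 1, 2 or 3, 3 without control 4, 1 without T2DM 1 or T2DM 2, and 2 without T2DM 3. Of 19 interferon-gamma response genes none passed (median log2 fold change -0.41). That list was called down (camera adjusted p = 1.9e-04; adjusted p = 0.492 with an estimated correlation). Its median was -0.25 without control 1 with the call kept, and -0.27 without T2DM 1 and T2DM 3 with the call lost (adjusted p = 0.197).

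B cell genes were lower while T cell genes stood near the control level. All 22 B cell identity genes had negative log2 fold changes, with a median of -0.91. The transcription factor gene Spib (log2 fold change -1.19 ± 0.18, edgeR adjusted p = 0.0183) fell, and 15 genes fell when adjusted over the list alone. Cd79b, a signalling chain of the B cell receptor, stood at 298 ± 86.3 CPM in control and 118 ± 39.1 in T2DM libraries (log2 fold change -1.33, edgeR adjusted p = 0.0654). The set test called it down (camera adjusted p = 3.2e-18; adjusted p = 0.346 with an estimated correlation), and its mean minus the control mean was -1.50 and -1.53 log2 units in T2DM 1 and T2DM 3, which held the most platelet RNA, against -0.83 in T2DM 2 and -0.35 in T2DM 4. Without T2DM 1 and T2DM 3 the median was -0.52 and the list stayed called (camera adjusted p = 9.6e-08). Of 21 T cell identity genes none passed (median log2 fold change -0.17). The T cell list was called down (camera adjusted p = 0.0209; adjusted p = 0.587 with an estimated correlation), and its mean did not differ by the exact permutation test (p = 0.4, difference -0.11 log2 units). That call was lost without control 1, control 4, T2DM 3 or T2DM 4 (adjusted p from 0.0682 to 0.200), with the covariates (0.0721) and without T2DM 1 and T2DM 3 (0.312). The median ran from -0.37 without control 2 to -0.031 without control 1. The B cell mean minus the T cell mean differed by -0.95 log2 units between T2DM and control libraries (exact permutation p = 0.0857).

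Cytotoxic and natural killer genes were lower in part. Of 20 cytotoxic effector genes, Ccl4 fell (log2 fold change -1.08), and 9 fell when adjusted over the list alone (median -0.61). Nkg7 and Gzmk had log2 fold changes of -0.63 and -0.97 (edgeR adjusted p of 0.0953 and 0.119). Camera called these genes down together (camera adjusted p = 1.9e-06; adjusted p = 0.344 with an estimated correlation). Of 20 natural killer genes, the inhibitory receptor gene Klra7 fell (log2 fold change -0.96), one of a family of near-identical receptor genes. Camera called the list down (camera adjusted p = 5.8e-05; adjusted p = 0.438 with an estimated correlation), although 2 members rose and 6 fell when adjusted over the list alone. Fry did not call the list (fry adjusted p = 0.151), and its mean did not differ by the exact permutation test (p = 0.171). The list mean minus the control mean was -0.67 and -0.77 in T2DM 2 and T2DM 4, which held the least platelet RNA. In T2DM 1 and T2DM 3 it was -0.094 and -4.3e-04, within the control range. Without T2DM 1 and T2DM 3 the median of -0.53 became -0.98.

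Some plasma cell genes were higher in T2DM. Of 15 genes tested, 3 rose: the immunoglobulin G constant genes Ighg1 (2.97 ± 0.845 to 36.1 ± 21.3 CPM; log2 fold change 3.61 ± 0.43) and Ighg2b (15.7 ± 2.63 to 64.2 ± 25.4 CPM; 2.03 ± 0.29), and the secretory transcription factor Xbp1 (0.65 ± 0.10). As a set these genes were called up (camera adjusted p = 0.0113; adjusted p = 0.438 with an estimated correlation; 0.0501 without T2DM 4). The call was also lost without haemoglobin, immunoglobulin and mitochondrial genes (median log2 fold change 0.059, adjusted p = 0.739) and with platelet and erythroid covariates (adjusted p = 0.120). Without scaling the median of 0.35 became -0.072, with the call kept.

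**Figure D4:**
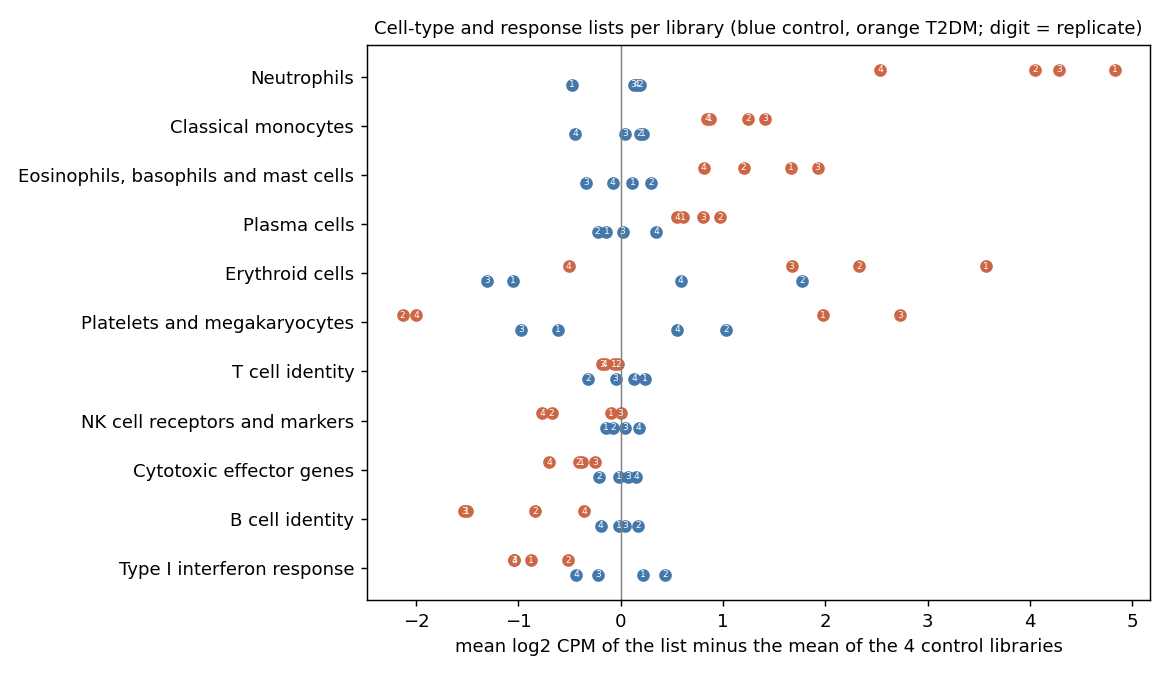
Mean log2 CPM of 11 gene lists per library, minus the mean of the 4 control libraries, blue for control and orange for T2DM, with the replicate number in each point. Neutrophil means lie 2.53 to 4.83 above the control mean in T2DM, and platelet means of T2DM libraries spread from -2.13 to 2.73.

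Over the 37 lists tested, 22 were called with camera's preset correlation, 13 up and 9 down. None was called with an estimated correlation, and fry called 8 of them and 1 other list. By the exact permutation test of list means none of the 37 passed, since the smallest p of 0.0286 adjusts to 0.0961 at best here; 11 lists had every T2DM library on one side of every control library.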

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

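The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries. Chance picks out a library in about 1 of 20 groups, and 13 of 266 groups examined held a library far from the other 3, against 13.3 expected by chance.

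Neutrophil list means of control libraries were between 2.16 and 2.22 log2 CPM except for control 1 at 1.55. The dendritic cell list mean was 2.78 in control 2, against 2.53 to 2.57 in the other control libraries. Edaradd stood at 11.4 CPM and Cecr2 at 12.05 CPM in control 3, above the other control libraries, and Cdkn1a at 33.1 CPM in control 3 against 19.1 to 19.6. In control 4, Vcan (3.29 CPM) and Per2 (4.71 CPM) were below and Ighg2c (13.5 CPM) above the other control libraries. In T2DM 2, Ifi27l2a (81.9 CPM) and Tyrobp (177.3 CPM) were above the other T2DM libraries, and Bst2 was highest in T2DM 3 (28.0 CPM). In T2DM 4, Mmp9 stood at 56.1 CPM against 245.2 to 274 in the other T2DM libraries, and Cd79b at 176.7 CPM against 95.8 to 101.9.

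Chance cannot be excluded for the gene counts by splits of the 8 libraries into 4 and 4. Of 35 splits, 2 gave as many changed genes as the real split, which gave 331; the highest other split gave 2204. The same held for genes higher (284 in the real split) and genes lower (47), for which 2 of 35 splits gave as many. The other split had 2119 genes in one direction and 85 in the other, and as a split and its mirror are one, the larger was counted for both. That other split sets control 1, control 3, T2DM 2 and T2DM 4 against the rest, which is the split of the 8 libraries by platelet list mean (at most 9.10 against at least 10.3 log2 CPM), so it points to a structure of the samples. The remaining 33 splits gave 0 genes. For gene lists, 1 of 35 splits, the real one, gave 22 called lists and the highest other gave 19. This met the bound set beforehand, but 1 of 35 is the smallest share these splits can give. Other splits also called many lists, so chance is not excluded for the lists either.

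Neutrophil genes were higher in T2DM. With platelet and erythroid list means as covariates, the group effect on the neutrophil list mean was 3.40 ± 0.42 (SE), which argues against carry-over of red cells and platelets as the whole cause. Without scaling beyond library size the median log2 fold change was 3.53, which argues against the scaling. Whether the T2DM libraries hold more of the same neutrophils as the controls or a different mix of stages cannot be told apart. The mean of 7 precursor granule genes minus that of 5 mature genes was 1.56 log2 units higher in T2DM than in control (exact permutation p = 0.0857). It was 2.41 higher (exact p = 0.0286) with another set of 7 mature genes tried on the same data. The precursor genes Mpo, Ngp, Lcn2, Camp and Ltf, and Ly6g of the first mature set, were among the 12 named genes with the largest increase. A positive difference thus follows in part from the choice of genes, so neither p-value shows a shift of stage. Other blood cells also express some mature genes in the control libraries. Diabetes, and how well granulocytes were removed from the PBMC, stay open and untested.

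Interferon-response genes were lower in T2DM. The median log2 fold change of the list was at its weakest -0.80, without control 1, whichever control library was left out, which argues against 1 control library with a high response. The list mean minus the control mean was 0.22, 0.44, -0.22 and -0.43 in control 1 to 4. In T2DM 1 to 4 it was -0.87, -0.51, -1.04 and -1.04, so control 4 lay close to T2DM 2. Leaving out 1 library cannot test for a high response in both control 1 and control 2. Dilution by the RNA of added granulocytes lowers all other cells alike. T cell identity genes had a median log2 fold change of -0.17 (SD 0.24) against -0.89 for interferon genes. This gap was 2.93 SD, and at least 2.06 SD in each other fit compared. Without scaling beyond library size the medians were -0.59 and -1.29. The SD is the spread among T cell genes, not between libraries, so the gap does not decide whether dilution is the whole cause. The first test tried, by library, left this open: the interferon mean minus the T cell mean differed by -0.76 log2 units, with overlapping groups (exact permutation p = 0.0571). Diabetes, and a rise of T cells among the other cells, stay open and untested as causes.

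B cell genes were lower in T2DM. With platelet and erythroid list means as covariates the group effect on the B cell list mean was -1.002 ± 0.249 (SE). The model gives each covariate 1 slope for both groups, so it cannot remove an effect present in the T2DM libraries alone. In T2DM 1 and T2DM 3, with the highest platelet means, the B cell mean minus the control mean was -1.50 and -1.53. In T2DM 2 and T2DM 4, with lower platelet means than any control library, it was still -0.83 and -0.35. More platelet RNA does not account for the fall there. Against the same T cell median of -0.17 (SD 0.24) the B cell median was -0.91, a gap of 3.03 SD (1.81 SD without T2DM 1 and T2DM 3). This SD too is among T cell genes, so the gap does not decide whether dilution by granulocyte RNA is the whole cause. The first test tried, by library, left this open here too, as the B cell mean minus the T cell mean differed by -0.95 log2 units with overlapping groups (exact permutation p = 0.0857). Diabetes, and a rise of T cells among the other cells, stay open and untested as causes.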

How the results depend on the processing

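The 331 called genes were followed through edgeR fits with median-of-ratios factors, no scaling, the covariates, the replicate block, fewer genes and each set of left-out libraries. Those tested kept their direction in all of these, 324 of them being tested without haemoglobin, immunoglobulin and mitochondrial genes, and kept an unadjusted p under 0.05 in all except without scaling (196 of 331). Their number past the adjusted threshold depended on the setting and on the libraries kept. It stayed within 1.5 times of 331 with median-of-ratios factors (277), limma-voom (294), no filter (258), a filter of 1 CPM in 4 libraries (340), a fold threshold (273) and without haemoglobin, immunoglobulin and mitochondrial genes (245). The fits without T2DM 1 and T2DM 3 and with platelet and erythroid covariates were chosen after seeing the data. None of the 89 genes followed singly changed sign under any setting in which it was tested, and 62 of them were called in the main fit. Called genes were chosen on these same libraries and had groups that did not overlap. Their kept signs and unadjusted p-values are therefore no separate evidence of stability. Depth limits low genes most in T2DM 1, and in simulations 14 of 100 genes changed 2-fold were recovered, so that uncalled genes with such changes are expected. Except where fewer libraries or a stricter threshold is itself the change, the cause of these differences was not tested.

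Without scaling beyond library size 41 genes passed, 40 higher and 1 lower, with 0 interferon genes (670 genes in edgeR at an unadjusted p under 0.05) and 2 monocyte genes. DESeq2 called 902 genes, 641 higher and 261 lower, with 13 interferon genes. At an adjusted p of 0.01, 9 genes passed, 9 higher and 0 lower, with 1 neutrophil, 0 interferon and 0 monocyte genes, and 14 lists. Genes lower numbered 31 without a filter, 31 without haemoglobin, immunoglobulin and mitochondrial genes, and 29 with a log2 fold change of at least 1. With the covariates 1355 genes passed, 1060 higher and 295 lower, 319 of them shared with the 331, and 18 interferon genes. Without T2DM 1 and T2DM 3, 2 interferon genes passed.

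With the replicate block in the model 0 genes passed, 0 higher and 0 lower, nor any neutrophil, interferon or monocyte gene (0 each; 1338 genes at an unadjusted p under 0.05 in edgeR). All 331 genes kept their direction and an unadjusted p under 0.05 with it, and the neutrophil median was 4.06. As these genes were chosen on the same libraries, that is no separate evidence. The labels name no batch, litter or day, so whether equal replicate numbers mark pairs is not known. The negative correlations between same-numbered libraries do not decide it. The other tools were not run with this block.

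Leaving out 1 library gave 0 to 542 genes changed, 0 to 445 higher and 0 to 97 lower, with 0 to 21 neutrophil, 0 to 4 interferon and 0 to 7 monocyte genes. The counts of 0 came without control 1 (1692 genes at an unadjusted p under 0.05 in edgeR) and without control 3 (1708), and 542 came without T2DM 4. The share of counts in mitochondrially encoded genes differed by -1.25 to 1.13 percentage points, negative without control 1, control 3 or T2DM 3. The ribosomal protein share differed by -1.85 to -0.70 and the haemoglobin share by 6.49 to 16.3 points. The immunoglobulin share differed by -0.342 to -0.204 and the 10 most abundant genes by 6.23 to 17.4 points, both at an exact p of 0.0286 without T2DM 4. With haemoglobin genes left out of the total the latter differed by 1.43 points (exact p = 0.714).

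With an estimated correlation 0 of 22 called lists stayed called, and fry kept 8 of them and called 1 more, the circadian clock list. The 8 kept were the chemokine receptor list and the 7 lists whose medians follow. List medians are the same in these tests: 4.42 (neutrophils), -0.89 (interferon), -0.91 (B cells), -0.61 (cytotoxic), 1.13 (monocytes), 0.78 (eosinophils, basophils and mast cells) and 0.35 (plasma cells). The plasma cell list also lost its call at an adjusted p of 0.01 (median 0.35), without haemoglobin, immunoglobulin and mitochondrial genes (0.059), with the covariates (0.46) and without T2DM 4, its median over left-out libraries being 0.22 to 0.64 and without scaling -0.072. The eosinophil, basophil and mast cell median was 0.30 without T2DM 3, 0.42 without T2DM 1, 0.38 without both and -0.087 without scaling, with the call kept.

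Directions of camera turned for the following lists, given by their median log2 fold change. None of them was called in its turned direction except the respiratory chain list (camera adjusted p = 0.0162), and only the erythroid, antioxidant, glycolysis and mitochondrial lists had been called before. Without T2DM 1 and T2DM 3 these were naive T cells (0.14), telomere (0.037), antioxidant (-0.24), glycolysis (-0.16), insulin (7.2e-04), cholesterol (0.13), respiratory chain (-0.16) and mitochondrially encoded genes (-0.15). With the covariates they were erythroid (-0.027) and p53 genes (0.074). The erythroid mean is itself a covariate there, so the model removes its group effect and that turn carries no information. Without scaling they were platelet (0.14), insulin (-0.30) and respiratory chain genes (-0.35). Platelet genes also turned with median-of-ratios factors (1.19), limma-voom (0.76), no filter (1.12), without haemoglobin, immunoglobulin and mitochondrial genes (1.11) and in fry (1.25). Dendritic cell genes turned with median-of-ratios factors (0.16), the 1 CPM filter (0.35) and fry (0.21). In fry p53 (0.048), unfolded protein (-5.6e-04) and cholesterol (0.013) genes turned. Over left-out libraries medians ran from -0.016 to 0.36 (dendritic), 0.20 to 1.63 (platelet), -0.051 to 0.12 (p53), -0.026 to 0.48 (immediate-early), -0.12 to 0.055 (unfolded protein) and -0.15 to 0.065 (cholesterol).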

Other observations

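The genes and families in this part were chosen after their values were seen. Of 11 tested Toll-like receptor genes, 7 had positive and 4 negative log2 fold changes, and Tlr13, Tlr4, Tlr5 and Tlr8 passed, with log2 fold changes of 1.20, 1.16, 2.33 and 1.38. All 12 C-type lectin genes of the Clec4 to Clec12 groups had positive log2 fold changes (median 1.23), and Clec4e, Clec4a2, Clec5a and Clec12a passed. The 3 tested genes of the Sirpb1 family, which share sequence, passed with log2 fold changes between 1.40 and 1.65. Ahr, a ligand-activated transcription factor, rose from 7.25 ± 1.03 to 28.3 ± 4.31 CPM (SD, n = 4 each), a log2 fold change of 1.96 ± 0.16 (edgeR adjusted p = 0.00687). Klra2 rose from 15.3 ± 0.513 to 39.2 ± 3.91 CPM, the opposite direction to Klra7.

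The lambda constant genes Iglc1 and Iglc2 fell, with log2 fold changes of -0.84 and -1.05, and Ighm, the heavy chain of IgM, stood at 1574 ± 243 CPM in control and 773 ± 89.4 in T2DM libraries (edgeR adjusted p = 0.125). Of 82 tested kappa V segments 68 had negative log2 fold changes, and of 80 heavy chain V segments 57 did, with 2 and 0 past the gene threshold. Rag1, needed for antigen receptor recombination, had 94 counts over the control libraries and 8 over the T2DM libraries (log2 fold change -2.93 ± 0.47, edgeR adjusted p = 0.0228). Of 11 tested genes of the Ifi200 family, 5 fell and 9 had negative log2 fold changes (median -0.99).

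Metabolic lists with called camera results had few called members. Of 20 glycolysis genes, the hexokinase gene Hk3 rose (log2 fold change 1.93), with the list called up (camera adjusted p = 0.00347; adjusted p = 0.569 with an estimated correlation). Of 20 antioxidant genes, Nfe2l2, which encodes NRF2, rose (log2 fold change 1.11; list adjusted p = 0.0115, and adjusted p = 0.569 with an estimated correlation). In the clock list Nfil3 (1.66) and Per2 (0.74) rose on the log2 scale, with the list not called by camera (adjusted p = 0.0742) but called up by fry (adjusted p = 0.0194), and its mean was higher in each T2DM than in each control library (exact permutation p = 0.0286, adjusted p = 0.0961). None of the 23 insulin and PI3K genes passed (camera adjusted p = 0.681), Irs1 having 49 counts over the control libraries and 9 over the T2DM libraries (edgeR adjusted p = 0.066). Of the other lists, camera called fatty acid oxidation (adjusted p = 0.0209) and mitochondrially encoded genes (0.0276) up, and MHC class II (1.2e-04), ribosomal protein (4.9e-09) and proliferation genes (0.0444) down, with 0 members of each past the gene threshold. With an estimated correlation their adjusted p values were 0.553, 0.635, 0.539, 0.539 and 0.569. Without T2DM 1 and T2DM 3, which held the most platelet RNA, these calls were lost for glycolysis (median log2 fold change -0.16), antioxidant (-0.24), mitochondrially encoded (-0.15), fatty acid oxidation (0.051), MHC class II (-0.19) and ribosomal protein genes (-0.072). In T2DM 1, 2, 3 and 4 the list mean minus the control mean was 1.10, 0.0042, 1.33 and -0.25 for glycolysis, 1.34, 0.11, 1.34 and -0.43 for antioxidant genes and 0.84, 0.022, 1.15 and -0.30 for mitochondrially encoded genes. It was 0.84, 0.35, 0.47 and -0.32 for fatty acid oxidation and -1.19, -0.29, -1.19 and 0.12 for MHC class II. For proliferation it was 0.21, -0.30, 0.30 and -0.27, so the T2DM libraries stood on both sides of the control mean. Leaving out 1 library ended the call for proliferation in 5 of 8 fits, for mitochondrially encoded genes in 4, for fatty acid oxidation in 2 and for antioxidant genes in 1. No scaling ended the calls for fatty acid oxidation, mitochondrially encoded and proliferation genes. The covariates ended those for antioxidant, fatty acid oxidation and proliferation genes, and the replicate block that for proliferation. For proliferation the median (-0.18) and mean (0.036) log2 fold change differ in sign.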
